A study of Mus musculus with 18 samples.

How the data were processed

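Hemibrains of mice homozygous for human APOE2, APOE3 or APOE4 were profiled at 12 months of age by polyA RNA-seq with a stranded single-end library kit, per the labels' protocols. The labels name 18 mice, 6 per genotype with 3 females and 3 males each, on a C57bl/6 strain background. Each mouse gave 1 library, and all libraries were pooled over the same lanes per the labels' protocols. Mice were grouped by the genotype and sex in the labels. Replicate numbers follow accession order and only name a mouse.

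The authors deposited raw read counts per gene symbol, and per the submitters' processing notes the reads were trimmed with Trimmomatic, aligned with STAR 2.7.0 to GRCm38/mm10, counted with featureCounts and compared with DESeq2. The annotation release, the strand setting of the counting and the DESeq2 model are not given in the sources used here. The authors also deposited a normalized signal, which per the file headers and the values is each raw count divided by 1 size factor per library. The mean signal, log2 fold change with its standard error, Wald score, p-value and adjusted p-value of the authors' DESeq2 comparisons of genotype pairs were deposited per the file headers. The count table held 52459 symbols, of which 26 had been turned into dates and were left out of library sizes and tests. These took 0.304% to 0.322% of the counts of a library. Symbols were matched to the GENCODE mouse release 21 annotation of GRCm38 for positions, and 47976 (91.5%) matched a single gene. Genes with no single match are given without a position.

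Library totals ran from 43818967 to 59394503 counts. With counts this deep, the spread between mice exceeded counting noise: the chi-square per degree of freedom between pairs of replicates of a genotype ranged from 5.77 to 46.55, so no pair looked like 1 library deposited more than once. The biological coefficient of variation was 0.085. Levels are given in CPM, which are counts scaled to library size, here after TMM scaling, as mean ± SD over the 6 mice of a genotype. Ratios against a group with few reads carry exact 95% intervals that cover counting error only, and folds against a group without reads use a floor of 3 reads summed over the group.

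The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the deposited raw counts, with robust estimation, TMM scaling, genes kept by filterByExpr and 1 fit of all 18 libraries with genotype and sex as additive terms. It tested 18891 genes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The sex by genotype interaction and the comparisons within a sex were taken from a fit with 1 mean per genotype and sex. Differences of gene lists fixed before the data were examined were tested with camera (limma 3.58.1) on voom log2 CPM with a preset inter-gene correlation of 0.01, adjusted over 46 lists per comparison, with an estimated correlation and fry beside it. These lists covered membrane trafficking, lipid handling, cell types, brain regions, and stress and immune responses. The lists described in the text were chosen after all list results were seen. Named genes follow a rule fixed before the data were examined. For each genotype pair it takes the 10 largest fitted increases and decreases among called genes with a mean of at least 1 CPM over the 12 libraries compared, leaving out predicted genes, and up to 4 members by smallest p for each list described. For the sex test and the interaction it takes the 10 smallest p values, and Apoe and the sex-linked genes are always included. Any other gene named was chosen after its values were seen. Some genes that the rule takes are not reported here.

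Alternatives fixed beforehand were DESeq2 size factors or upper-quartile factors in place of TMM, no filter on low counts, at least 1 CPM in 6 libraries, DESeq2 1.42.0, limma voom, no sex term, 1 surrogate variable (sva 3.50.0), camera on ranks, fits of the compared libraries alone, a fit of the APOE3 and APOE4 mice whose titles end in the letters e or f, which the labels do not explain and which no APOE2 title shares, glmTreat against a fold change of 1.2, an adjusted p under 0.01, and leaving out each library in turn. Counts outside chromosome windows with an excess of called genes were added after the data were seen. The genome was divided into windows of 10 Mb, and an excess of called genes was tested by hypergeometric p adjusted over 272 windows. Neighbouring pairs of called genes were compared with 10000 random reassignments of the calls. Copies of genes were found with blastn 2.17.0 between the longest annotated transcripts, on the same strand, at a minimum identity of 90% over at least 50% of the query.

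Tests were checked on simulated counts of 18891 genes for all 18 libraries at their own sizes. Counts were drawn from the fitted APOE3 means and sex differences, with changes planted in the APOE2 libraries. Each gene was drawn independently, so the share of false calls in the real data may differ. In the APOE2 against APOE3 simulation edgeR called 46% of genes planted at a fold of 1.25, 78% at 1.5, 90% at 2 and 98% at 4. Of its simulated calls 6.6% were false, against 11.5% for DESeq2 and 4.8% for limma voom. Plots were drawn with matplotlib 3.10.9.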

Results

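Gene expression was measured by polyA RNA-seq in hemibrains of 18 mice aged 12 months in which the mouse Apoe gene had been replaced by human APOE2, APOE3 or APOE4, the common isoforms of the lipid carrier apolipoprotein E. Each genotype had 6 mice, 3 females and 3 males. The total count per library ran from 49545646 to 59394503 in APOE2, from 43818967 to 50382463 in APOE3 and from 48841442 to 52761314 in APOE4. Mitochondrial transcripts took 3.31% to 4.73% of counts in APOE2 libraries, 3.35% to 3.83% in APOE3 and 3.21% to 4.44% in APOE4. The title of the series concerns APOE2, the loss of neuronal endosome function with aging and the secretion of exosomes, so genes of these compartments were among the groups compared.

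Reads on the mouse Apoe entry (chromosome 7, 19696109 to 19699188, GRCm38) were similar in level across genotypes, at 39.46 ± 2.48 CPM in APOE2, 42.37 ± 3.13 CPM in APOE3 and 44.89 ± 5.19 CPM in APOE4 (SD, n = 6). No genotype pair passed the test, with adjusted p = 0.451 for APOE2 against APOE3, 0.104 for APOE2 against APOE4 and 0.825 for APOE4 against APOE3 (edgeR). The entry holds only reads that aligned to the mouse reference, so it is not the level of the human transcript and does not identify the isoform.

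Principal components of log2 CPM set the APOE2 mice apart from the others. On the first component, with 27.5% of the variance, the 6 APOE2 libraries lay between -34.2 and -22.7 and the APOE3 and APOE4 libraries between 8.43 and 21.7. None of the APOE2 sample titles ends in a letter found in the titles of the other genotypes, so a difference that goes with those unexplained letters could not be separated from the APOE2 genotype. The second component, with 13% of the variance, was positive in the 9 females and negative in the 9 males.

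**Figure D1:**
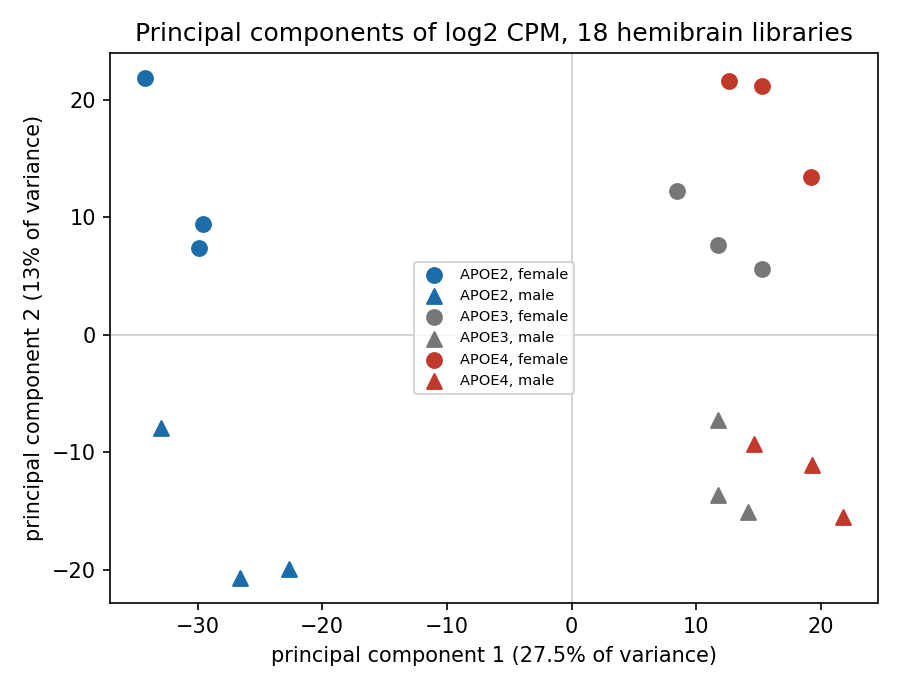
Scores of the 18 libraries on the first and second principal components of log2 CPM, 1 point per mouse, coloured by genotype, with circles for females and triangles for males. The 6 APOE2 libraries lie at -22.7 or below on the first component, and all APOE3 and APOE4 libraries lie at 8.43 or above.

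APOE2 mice were compared with APOE3 mice, the common human allele, to ask how the protective isoform changes the aging brain. Hspa8, the constitutive HSC70 chaperone that uncoats clathrin vesicles, fell from 245 ± 20 CPM in APOE3 to 30.8 ± 3.27 CPM in APOE2 (log2 fold change -2.99, SE 0.07, adjusted p = 2.74e-18, n = 6 each). Its level is uncertain, because reads on its near-identical copies rose from 1.92 to 110 CPM and the summed counts had a log2 fold change of -0.81 (SE 0.06). Xaf1, an interferon-induced pro-apoptotic factor, stood at 5.67 ± 0.166 CPM in APOE3 and rose by 2.40 on the log2 scale (SE 0.06), and Pla2g4e, a cytosolic phospholipase A2, rose from 14.2 ± 1.5 to 69.4 ± 6.75 CPM. Masp2, a protease of the lectin complement pathway, rose by 2.46 on the log2 scale (SE 0.19), Mns1, a protein of motile cilia, by 1.67 (SE 0.09) and Sytl1, a Rab27-binding protein of vesicle docking, by 1.55 (SE 0.11). Oscar, an osteoclast-associated immunoglobulin-like receptor, rose by 3.76 (SE 0.20), and the immunoglobulin kappa constant region Igkc rose by 1.83 (SE 0.31). For Oscar it was APOE3 that stood apart, at 0.159 ± 0.05 CPM against 2.18 ± 0.439 CPM in APOE2 and 2.48 ± 0.357 CPM in APOE4.

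The other decreases in APOE2 that the naming rule takes were in genes that are scarce in whole brain. Bfsp2, a lens filament protein, stood at 4.19 ± 0.306 CPM in APOE3 and 0.259 ± 0.107 CPM in APOE2. The mitotic checkpoint kinase Bub1b had a log2 fold change of -3.62 (SE 0.20), the chemokine Ccl28 of -3.30 (SE 0.36), the CD30 receptor gene Tnfrsf8 of -3.17 (SE 0.18), the lipoxygenase Alox8 of -2.10 (SE 0.09) and the doublecortin family member Dcdc2b of -2.03 (SE 0.15). AC165261.1 and AC157516.1, which had no single match in the annotation, were lower, with log2 fold changes of -7.06 (SE 0.18) and -2.99 (SE 0.19). Zfp990, a zinc finger gene, was higher, at 2.35 ± 0.530 CPM against 0.0658 ± 0.0255 CPM, and is uncertain as a member of a multigene family, since the assignment of its reads was not tested. Of the 20 genes that the naming rule takes, which leaves out predicted genes such as the copies Gm15459 and Gm3650 outside the windows, 14 lay in 10 Mb windows of the chromosomes that held an excess of called genes: Hspa8, Xaf1, Pla2g4e, Masp2, Mns1, Sytl1, Bfsp2, Bub1b, Ccl28, Tnfrsf8, Alox8, Dcdc2b, Zfp990 and the translation factor gene Eif3j1. In all, 738 of 18891 genes passed, 359 higher and 379 lower in APOE2, and 210 of them changed by more than 2-fold. At an unadjusted p under 0.05 there were 3179 genes. Within females 382 genes were called and within males 368, and no gene was called by edgeR for a difference of this comparison between the sexes, where 1094 had an unadjusted p under 0.05, DESeq2 called 4 and limma voom 0.

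Choroid plexus genes, which make cerebrospinal fluid, stood higher in APOE2 than in APOE3 for 20 of 20 members measured, with a median log2 fold change of 0.43. The prolactin receptor Prlr rose from 12.7 ± 3.21 to 21.9 ± 6.98 CPM (adjusted p = 0.0691 with no sex term), Calml4, which lies in a window with an excess of called genes on chromosome 9, from 2.44 ± 0.477 to 4.03 ± 1.16 CPM and the collagen gene Col8a1 from 5.91 ± 0.877 to 8.18 ± 1.2 CPM, and 4 members passed over all genes and 12 when adjusted over the list alone. Camera gave an adjusted p = 5.34e-08 with the preset correlation and an adjusted p = 0.82 with an estimated correlation. As a list these genes stood lowest in APOE3, since 20 of 20 were also higher in APOE4 than in APOE3, with a median of 0.19. Immediate early genes, transcribed within minutes of neuronal activity, had lower values in APOE2 than in APOE3 in 18 of 19 members, with a median of -0.79. Their camera adjusted p was 2.83e-07, against an adjusted p = 0.82 with an estimated correlation. No member passed over all genes in edgeR, where 12 had an unadjusted p under 0.05, DESeq2 called 6 and limma voom 2. Of the members, 11 passed when adjusted over the list alone, and Nr4a1 stood at 89.2 ± 47.4 CPM in APOE3 and 42.2 ± 14.0 CPM in APOE2.

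Among microglial genes, Selplg, a selectin ligand of resting microglia, fell from 28.7 ± 1.91 to 22.2 ± 1.17 CPM, and the lysosomal protein Laptm5 from 36.1 ± 1.87 to 28.7 ± 1.86 CPM. The homeostatic microglia list was called lower (adjusted p = 0.0105; adjusted p = 0.82 with an estimated correlation), with 3 members called over all genes and 5 adjusted over the list alone. The disease-associated microglia list was called higher (adjusted p = 0.0458; adjusted p = 0.82 with an estimated correlation), with 2 members higher over all genes and 6 higher and 1 lower adjusted over the list alone, among them the integrin Itgax, which rose from 0.600 ± 0.180 to 1.30 ± 0.231 CPM. In the reactive astrocyte list (higher, adjusted p = 0.0190; adjusted p = 0.82 with an estimated correlation), Gfap, the main astrocyte filament, rose from 200 ± 20.6 to 256 ± 32.3 CPM and Cd109 by 0.83 on the log2 scale (SE 0.12), and 3 members were called over all genes and 5 adjusted over the list alone. Cholesterol biosynthesis genes were called lower (adjusted p = 0.0166; adjusted p = 0.82 with an estimated correlation): the desaturase Sc5d fell by 0.35 (SE 0.05), while Hmgcs1, a synthase early in the pathway, rose by 0.30 (SE 0.06). Adjusted over the list alone, 1 cholesterol gene was higher and 2 were lower. Laptm5, Cd109, Sc5d and Hmgcs1 lie in windows with an excess of called genes, whereas Selplg, Itgax and Gfap do not.

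Genes of early endosomes and Rab GTPases, which direct endosome traffic, were called higher in APOE2 than in APOE3 by camera (adjusted p = 0.0186; adjusted p = 0.82 with an estimated correlation). Of 34 members, Rab4a, a GTPase of fast recycling, rose by 0.23 on the log2 scale (SE 0.05), and the Rab5 effector Rabep1 rose by 0.19 (SE 0.05); these 2 also passed when adjusted over the list alone. The call of Rabep1 was lost without APOE2 replicate 1 (adjusted p = 0.0545), APOE2 replicate 2 (0.0547), APOE3 replicate 4 (0.0540) or APOE3 replicate 5 (0.0649). The list of exosome biogenesis and release was not called in any genotype pair, with adjusted p = 0.695 for APOE2 against APOE3, 0.861 for APOE2 against APOE4 and 0.796 for APOE4 against APOE3. Of its 38 measured members edgeR called Anxa6, a membrane-binding annexin, in APOE2 against APOE3, where it fell by 0.18 (SE 0.04), and DESeq2 called 2 members. Rabep1 and Anxa6 lie in windows with an excess of called genes on chromosome 11, and Rab4a lies outside the windows. Lists of the retromer (adjusted p = 0.287), ESCRT (0.287) and the lysosome (0.878) were not called in that comparison either.

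Other lists called higher in APOE2 than in APOE3 were those of mitochondrially encoded genes (adjusted p = 8.82e-04, 7 of 7 members positive), the thalamus (0.00525), blood (0.0251) and oligodendrocytes (0.0258). The genes beside Apoe were called lower (0.0191), and 1 of 57 passed, the incretin receptor Gipr. With an estimated correlation each had an adjusted p = 0.82. In all, camera called 12 of 46 lists with the preset correlation and 0 with an estimated one, where 1 list had an unadjusted p under 0.05. On ranks camera called 14, and directional fry called 0, with 10 at an unadjusted p under 0.05.

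Called genes lay beside one another on the chromosomes. Of 700 called genes with a position, 358 (51.1%) lay in 18 windows of 10 Mb that held 10.9% of the tested genes, on chromosomes 2, 4, 7, 9, 11 and 13. In the window from 140 to 150 Mb of chromosome 4, which holds Tnfrsf8, Zfp990 and Masp2, 50 of 108 tested genes were called, 20 higher and 30 lower in APOE2. On chromosome 9 between 40 and 50 Mb, where Hspa8 lies (40800984 to 40810087), 31 of 101 were called, and on chromosome 2 between 120 and 130 Mb, which holds Pla2g4e and Eif3j1, 34 of 130. There were 146 neighbouring pairs of called genes, against a median of 27 and at most 47 in permuted calls (permutation p = 1e-04, the smallest that 10000 permutations can give). In windows defined on females alone, 51% of the genes called in males were found, and these windows held 8.4% of the genes tested. Outside the windows lay 342 called genes, and another 38 had no position; of these 380 together, 204 were higher and 176 lower. Within 5 Mb of Apoe itself 2 of 115 genes were called, an odds ratio of 0.442 (Fisher's exact test, two-sided p = 0.331), and within 10 Mb 17 of 263, an odds ratio of 1.75 (p = 0.0339). The window from 20 to 30 Mb of chromosome 7, which begins just past Apoe, held 22 called of 152 tested genes (hypergeometric adjusted p = 2.83e-06).

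**Figure D2:**
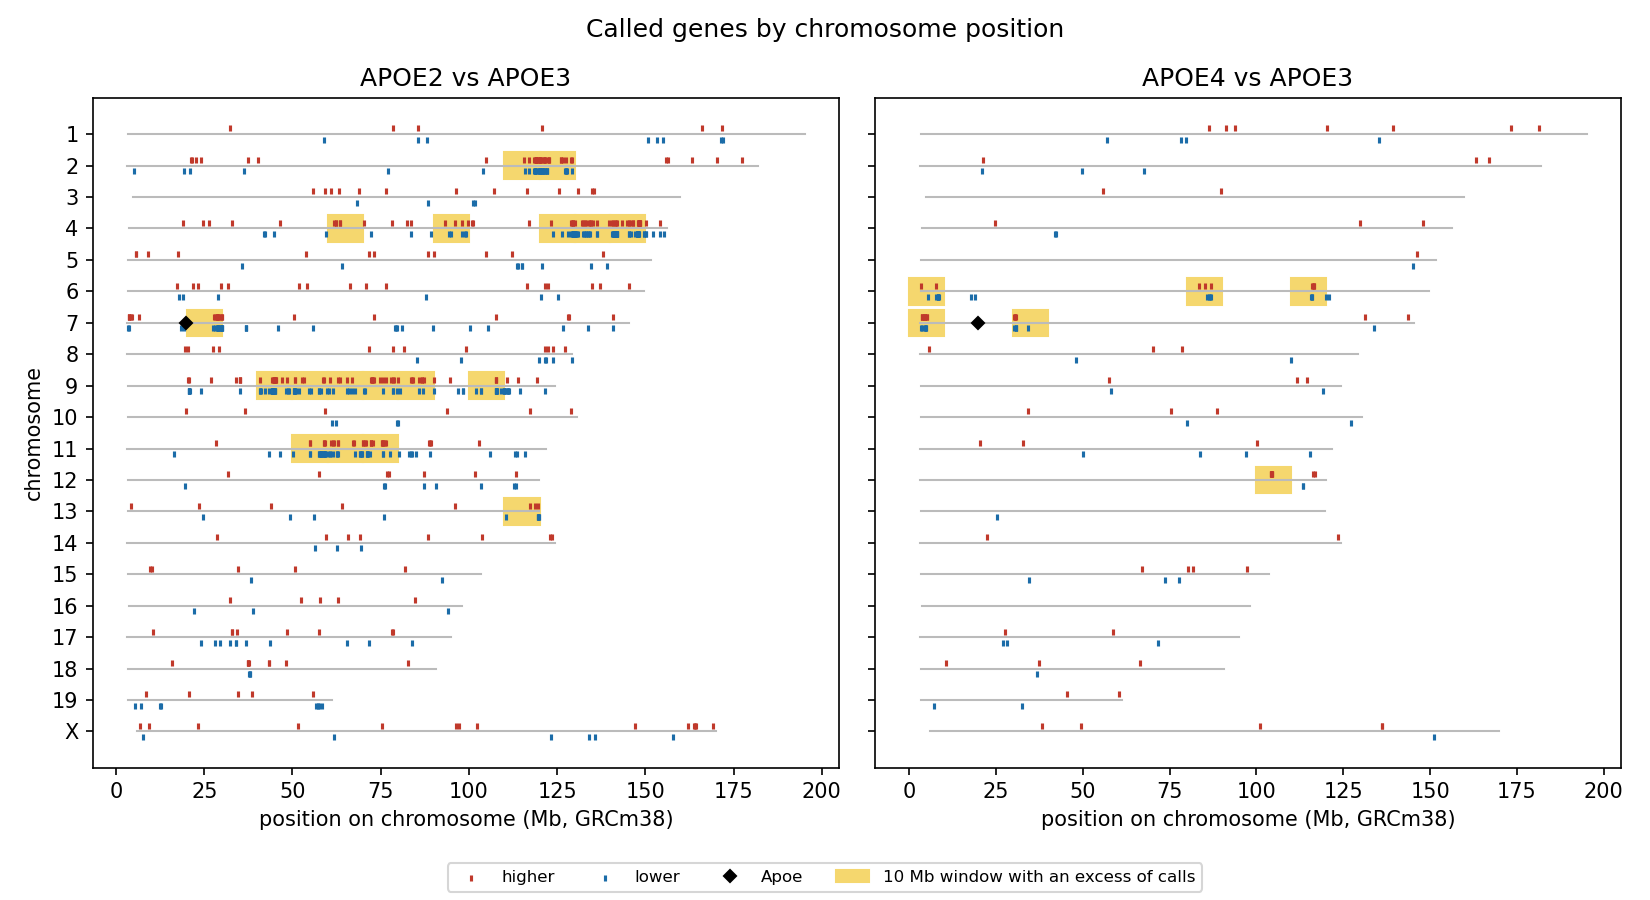
Positions along the chromosomes, in Mb, of the genes called in APOE2 against APOE3 and in APOE4 against APOE3, with the 10 Mb windows that hold an excess of called genes shaded. In APOE2 against APOE3, 358 of 700 called genes lie in 18 windows on chromosomes 2, 4, 7, 9, 11 and 13.

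Several genes that fell in APOE2 had a near-identical copy elsewhere that rose, so their counts are uncertain. Reads of Hspa8 copies stood at 1.92 CPM in APOE3 and 110 CPM in APOE2, most of them on Gm15459 on chromosome 5 (log2 fold change 7.37). The summed counts of Hspa8 and its 4 copies were still lower in APOE2, by a log2 fold change of -0.81 (SE 0.06). The translation factor gene Eif3j1 fell by 2.54 (SE 0.09) while its copy Eif3j2 rose from 0.0887 ± 0.0557 to 4.83 ± 0.550 CPM, and their sum had a log2 fold change of -0.34 (SE 0.07). Eno1, the glycolytic enolase, had a log2 fold change of -1.57, its copy Eno1b rose from 0.103 ± 0.0760 to 11.7 ± 0.771 CPM, and their sum had a log2 fold change of -1.30 (SE 0.05). For Gm3650, the copy of Spg11, 136 reads in APOE2 against 0 in APOE3 made it at least 40.2-fold higher against a floor of 3 reads over the group. Of 23 copies outside the windows that rose in APOE2, 19 (82.6%) had their parent gene inside a window, compared with 34 of 566 other copies (6%; Fisher's exact test, two-sided p = 3.17e-18). The parent was called lower for 10 of these 23 and for 83 of the 566 (odds ratio 4.46; Fisher's exact test, two-sided p = 0.00117). Copies of 1 parent are not independent in these tests. Gapdh, called lower with an edgeR adjusted p = 0.0469, had 76 matched copies, so the 83 may rest largely on it. In APOE2 against APOE4 the parent was called lower for 9 of 26 risen copies and 27 of 570 others (odds ratio 10.5). The copies and parents named here were chosen after their values were seen, apart from those that the rule names.

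**Figure D3:**
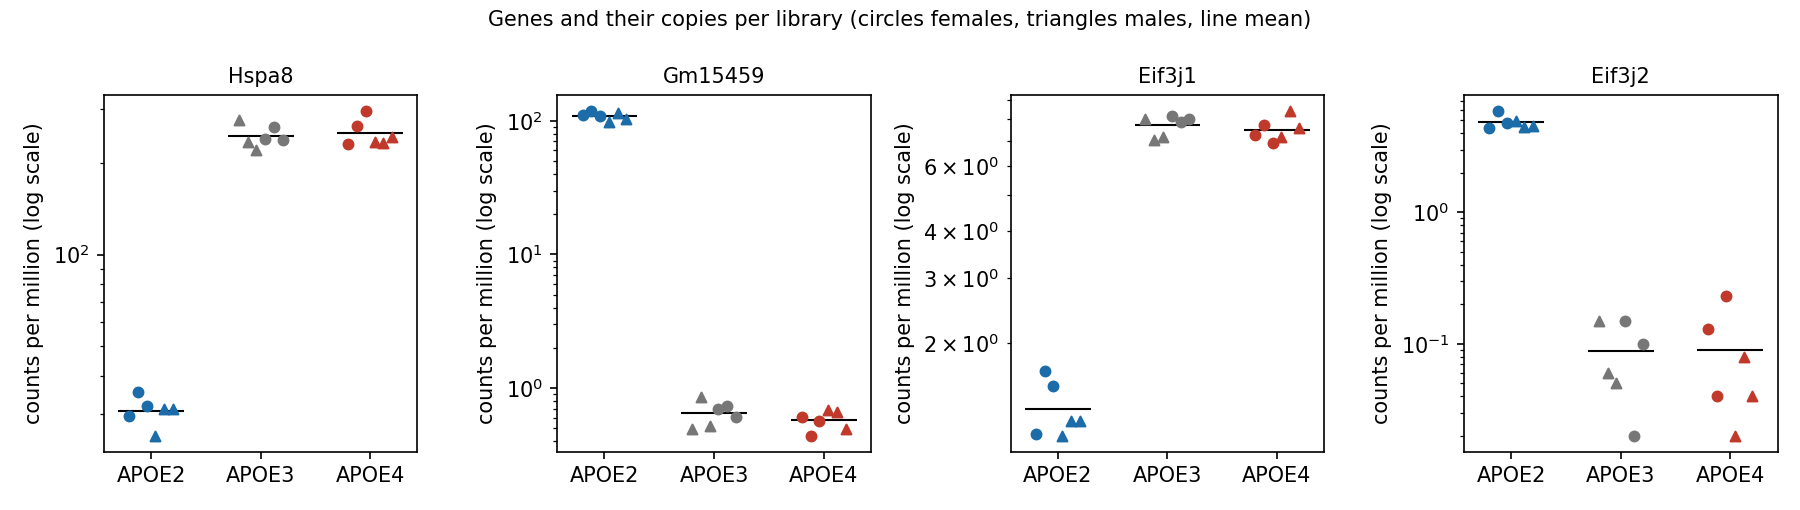
Levels of Hspa8, its copy Gm15459, Eif3j1 and its copy Eif3j2 in CPM on log axes, 1 point per mouse, circles for females and triangles for males. In APOE2 the parent genes lie lower and the copies higher than in APOE3 and APOE4.

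APOE4 mice were compared with APOE3 mice to ask what the isoform linked to Alzheimer's disease risk changes. Serpina3n, an acute-phase protease inhibitor that astrocytes express in injury, rose from 21.2 ± 1.28 CPM in APOE3 to 142 ± 6.70 CPM in APOE4 (log2 fold change 2.74, SE 0.06, adjusted p = 1.57e-19, n = 6 each). Its neighbours in the Serpina3 cluster of chromosome 12 rose with it. Serpina3f had 1420 reads in APOE4 and 4 in APOE3, a ratio of 330 (95% interval 129 to 1210), and Serpina3m had 1225 and 6, a ratio of 190 (87 to 519). Serpina3k had 199 reads in APOE4 and 0 in APOE3, at least 61.7-fold higher against a floor of 3 reads over the group; it shares a start position with Serpina3m, and reads of this gene family are uncertain. Serpina3k was chosen after its values were seen.

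Wdfy1, an endosomal protein that binds phosphatidylinositol 3-phosphate, fell from 62.3 ± 1.95 CPM in APOE3 to 20.2 ± 1.53 CPM in APOE4 (log2 fold change -1.63, SE 0.05). On chromosome 7, Eps8l1, an actin regulator, rose from 0.700 ± 0.103 to 9.86 ± 3.84 CPM, the phosphatase Ptprh by 3.15 on the log2 scale (SE 0.20), Oscar by 3.95 (SE 0.20) and the channel-like gene Tmc4 by 1.31 (SE 0.16), while the retinol dehydrogenase Rdh13 had a log2 fold change of -0.76 (SE 0.07), the kinase Sbk3 of -0.71 (SE 0.14) and the neighbouring epidermal genes Dmkn and Sbsn of -1.18 (SE 0.13) and -0.83 (SE 0.12). For Oscar and Tmc4 it was APOE3 that stood apart. Oscar was at 2.18 ± 0.439 CPM in APOE2 and 2.48 ± 0.357 CPM in APOE4. Tmc4 was at 5.84 ± 1.42 CPM in APOE2, 2.65 ± 0.522 CPM in APOE3 and 6.54 ± 1.06 CPM in APOE4. Crb1, a cell polarity protein, rose by 1.73 (SE 0.13) and Tmem72 by 1.35 (SE 0.24; adjusted p = 0.0653 in mice with title letters e or f alone). The adhesion gene Ninj2 had a log2 fold change of -1.25 (SE 0.12). The immunoglobulin constant regions Ighg2c and Ighm, both on chromosome 12, had log2 fold changes of -5.72 (SE 0.26) and -0.82 (SE 0.09). CT030173.1 and AC158232.1, which had no single match in the annotation, had log2 fold changes of -0.75 (SE 0.11) and -0.83 (SE 0.18). The call of AC158232.1 was lost with no sex term (adjusted p = 0.114), in limma voom (0.101) and without APOE3 replicate 1, 2, 3 or 4 or APOE4 replicate 3, 4, 5 or 6 (up to 0.0875). Erdr1 had 1450 reads in APOE4 and 206 in APOE3, a ratio of 6.55 (95% interval 5.66 to 7.62, which covers counting error only). Mice varied more than that, at 4.78 ± 1.75 CPM in APOE4 and 0.711 ± 0.628 CPM in APOE3 (edgeR log2 fold change 2.74, SE 0.44). The call of Erdr1 was lost without APOE2 replicate 4 (adjusted p = 0.0679), in the 12 libraries compared alone (0.0625) and in mice with title letters e or f (0.135). In all 146 genes were called, 81 higher and 65 lower in APOE4, and 1658 had an unadjusted p under 0.05. DESeq2 called 261. Within females 80 genes were called, with 48 without APOE3 replicate 5 and 51 without APOE4 replicate 3, and within males 67, with 37 without APOE3 replicate 3 and 38 without APOE3 replicate 1. Of 140 with a position, 52 (37.1%) lay in 6 windows on chromosomes 6, 7 and 12 that held 3.2% of tested genes, with 18 neighbouring pairs against a median of 1 in permuted calls (permutation p = 1e-04, the smallest possible), while 88 called genes lay outside the windows and 6 had no position. Among the named genes, the Serpina3 genes, Eps8l1, Ptprh, Oscar, Tmc4, Rdh13, Sbk3, Dmkn, Sbsn and Tmem72 lay in these windows, and Wdfy1, Crb1, Ninj2, Ighg2c and Ighm did not. The windows have fixed edges, and Ninj2 begins at 120093350, just past the chromosome 6 window from 110 to 120 Mb. The chromosome 7 windows, from 0 to 10 Mb and from 30 to 40 Mb, lie on either side of Apoe. They held 15 called of 93 tested genes and 9 of 111, while 0 of 263 genes within 10 Mb of Apoe were called.

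**Figure D4:**
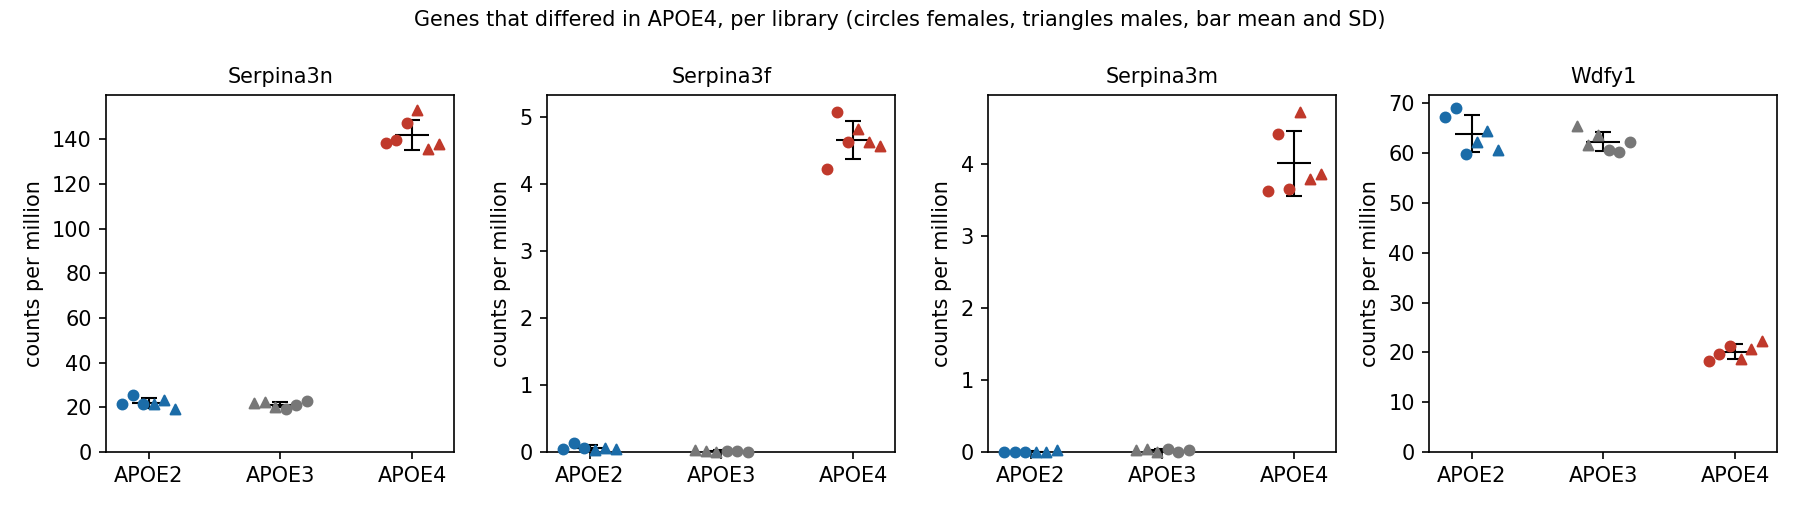
Levels of Serpina3n, Serpina3f, Serpina3m and Wdfy1 in CPM, 1 point per mouse, circles for females and triangles for males, with the mean and SD of each genotype. Serpina3n averages 142 CPM in APOE4 and 21.2 CPM in APOE3.

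Oligodendrocyte and myelin genes stood higher in APOE4 than in APOE3 for 23 of 23 members, with a median log2 fold change of 0.17. Gpr37, a receptor of oligodendrocytes, stood at 91.5 ± 9.43 CPM against 77.4 ± 5.28 CPM; no member passed over all genes in edgeR, DESeq2 or limma voom, 11 had an unadjusted p under 0.05 in edgeR and 2 passed when adjusted over the list alone. Camera gave the list an adjusted p = 2.37e-10, and an adjusted p = 0.566 with an estimated correlation. The list of the unfolded protein and integrated stress responses was called higher (adjusted p = 0.00306; adjusted p = 0.948 with an estimated correlation), with the stress-induced transcription factor Atf4 rising from 100 ± 4.28 to 131 ± 7.35 CPM and 2 members called over all genes, 4 higher and 1 lower adjusted over the list alone. Nuclear genes of oxidative phosphorylation were called lower (adjusted p = 0.00679; adjusted p = 0.948 with an estimated correlation), with 2 of 82 members called and a median of -0.02. The reactive astrocyte list was called higher (adjusted p = 0.0463; adjusted p = 0.948 with an estimated correlation), and this call rests on Serpina3n: the other 25 members, 14 of them positive, had a camera p = 0.293.

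Further lists called higher in APOE4 than in APOE3 were the choroid plexus (adjusted p = 2.88e-04), interferon response (0.0119), hindbrain (0.00679), olfactory bulb (0.00679), meningeal fibroblasts (0.00679), heat shock (0.0380) and the pituitary (0.0232), and homeostatic microglia (0.00613) and excitatory neurons (0.0460) were called lower. With an estimated correlation the adjusted p was 0.200 for the hindbrain, 0.566 for excitatory neurons and 0.948 for the others. Without genes in windows, camera with the preset correlation no longer called excitatory neurons (adjusted p = 0.0585) or reactive astrocytes (0.576). It then called mitochondrially encoded genes higher (0.0479, against 0.0519 with all genes). Growth hormone, Gh, a pituitary transcript, reached 132 CPM in APOE4 replicate 5, and without this library camera called 8 lists in place of 13.

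APOE2 and APOE4 mice differed in 1233 genes, 568 higher and 665 lower in APOE2, with 3824 at an unadjusted p under 0.05. Without APOE4 replicate 5 the count was 1903. Hspa8 had a log2 fold change of -3.02, against -0.84 (SE 0.06) for its summed counts with its copies, Xaf1 of 2.28 (SE 0.06), Pla2g4e of 2.50 (SE 0.13), Masp2 of 2.83 (SE 0.19), Sytl1 of 1.94 (SE 0.11), Bfsp2 of -3.81 (SE 0.18), Bub1b of -3.68 (SE 0.20) and Ccl28 of -3.65 (SE 0.36). Fxyd2, a regulator of the sodium pump, rose from 2.19 ± 0.290 CPM in APOE4 to 7.94 ± 1.25 CPM in APOE2. Ighg2c was higher in APOE2 by 5.83 (SE 0.26), and Eps8l1 and Ptprh had log2 fold changes of -3.78 (SE 0.21) and -3.30 (SE 0.20). Serpina3m had 1 read in APOE2 and 1225 in APOE4, a ratio of 1290 (95% interval 231 to 50900), and Erdr1 had 1 and 1450, a ratio of 1520 (273 to 60200). Within females 539 genes were called and within males 454. The male count was lower when the compared libraries were fitted alone, and another split of the male libraries gave 678. Of 1179 called genes with a position, 385 (32.7%) lay in 15 windows that held 9.5% of tested genes, with 219 neighbouring pairs against a median of 76 in permuted calls, while 794 called genes lay outside the windows and 54 had no position. Hspa8, Pla2g4e, Masp2, Sytl1, Bfsp2, Bub1b and Fxyd2 lay in these windows. Xaf1 and Ccl28 lay outside them but in windows of APOE2 against APOE3. Eps8l1, Ptprh and Serpina3m lay outside them but in windows of APOE4 against APOE3. A place outside the windows of 1 comparison therefore does not exclude a regional difference.

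Immediate early genes were lower in APOE2 than in APOE4 in 19 of 19 members, with 6 called over all genes and 14 adjusted over the list alone. Egr1, an activity-induced transcription factor, fell from 272 ± 59 CPM to 141 ± 32.4 CPM and the phosphatase gene Dusp6 from 58.2 ± 4.75 to 40.2 ± 7.18 CPM. Camera gave the list an adjusted p = 9.67e-09, and an adjusted p = 0.949 with an estimated correlation. Interferon response genes were called lower (adjusted p = 0.00133; adjusted p = 0.949 with an estimated correlation), with 8 members lower, among them the antiviral tetherin gene Bst2 at -0.56 (SE 0.12), and Xaf1 the single one higher; adjusted over the list alone 13 were lower and 1 higher. Cholesterol biosynthesis genes were called lower (adjusted p = 0.0454; adjusted p = 0.949 with an estimated correlation): Sc5d fell by 0.38 (SE 0.05), and adjusted over the list alone 4 were lower and 1 higher. Lists of the thalamus (0.00831), blood (0.00944), oxidative phosphorylation (0.0222), choroid plexus (0.0369) and disease-associated microglia (0.0419) were called higher, each with an adjusted p = 0.949 with an estimated correlation. Without genes in windows, camera with the preset correlation no longer called cholesterol biosynthesis (adjusted p = 0.0974) or disease-associated microglia (0.0665). In the choroid plexus list Calml4 rose by 0.63 (SE 0.16) and Tmem72 had a log2 fold change of -0.95 (SE 0.23). The early endosome list was not called in this comparison (adjusted p = 0.178), although Rab4a was higher by 0.29 (SE 0.05) and Rabep1 by 0.22 (SE 0.05). In the exosome list Anxa6 was lower at -0.19 (SE 0.04) and Sytl4, a Rab27 effector, was higher by 0.54 (SE 0.16, adjusted p = 0.0446). The call of Sytl4 held without APOE2 replicate 3 or 6, APOE3 replicate 4 or APOE4 replicate 1 or 5 and was lost without any of the other 13 libraries (adjusted p up to 0.105). It was also lost without a filter on low counts (0.131), with no sex term (0.142) and in the 12 libraries compared alone (0.0919).

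The comparisons of APOE2 and APOE4 with APOE3 share the APOE3 libraries. In both, 12 genes were higher and 11 lower, and 5 went opposite ways, where independent lists of these sizes give 1.54 and 1.30. The correlation of log2 fold changes across genes was 0.161, below the 0.504 of simulated unchanged groups with shared controls, and the covariance was 0.0148 against a simulated 0.0112. With the APOE3 libraries split between the comparisons, 12 and 14 genes were shared in the 2 splits, and the covariance was 0.00138 and 0.00883. For APOE2 against APOE3 and APOE2 against APOE4, which share the APOE2 libraries, 232 genes were higher and 298 lower in both and 0 went opposite ways, where independent lists give 10.8 and 13.3; the correlation was 0.839 against a simulated 0.494, and the covariance 0.140 against 0.0109. With the APOE2 libraries split, 141 and 182, or 137 and 170, genes were shared. Genes are not independent replicates in these correlations.

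Genes of the sex chromosomes separated the labelled sexes. Of 25 genes called between females and males, 16 were higher and 9 lower in females, and 1599 had an unadjusted p under 0.05. DESeq2 called 55, and 53 were called without a filter on low counts. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y were lower in females, with log2 fold changes from -10.11 to -9.94, and Xist, the RNA that silences an X chromosome, was higher by 10.11 (SE 0.16). The X-linked genes Eif2s3x, Kdm6a, Kdm5c and Ddx3x, which escape X inactivation, rose by 0.61 (SE 0.05), 0.45 (SE 0.04), 0.43 (SE 0.04) and 0.37 (SE 0.05). The interaction of sex and genotype gave 0 genes in edgeR, where 988 had an unadjusted p under 0.05, DESeq2 called 24 and limma voom 1. In edgeR 239 were called without a filter on low counts and 4 without APOE4 replicate 1.

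Set against the authors' deposited tables, log2 fold changes had Spearman correlations across genes of 0.9995, 0.9999 and 0.9998 for APOE2 against APOE3, APOE2 against APOE4 and APOE4 against APOE3. At the same adjusted p, the authors' deposited tables held 921, 1502 and 253 called genes, and 723, 1215 and 146 of these were called here in the same direction.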

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

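The test for single far values was chosen before the data were examined, and the genes it covers follow the rule for named genes. It asks whether the gap of the highest or lowest of 6 libraries to the next one is, as a share of the range of the group, above the 95% critical value of Dixon, and chance gives about 1 such group in 20. It covered 192 groups, which were the levels of the rule-named, sex-linked and interaction genes and Apoe, the library totals and the mitochondrial share, and 14 groups had a far value.

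Apoe stood apart in 2 groups, at 36.6 CPM in APOE3 replicate 3 against 42 to 45.1 CPM in the other 5 libraries, and at 54.9 CPM in APOE4 replicate 4 against 40 to 44.8 CPM. Dmkn was high in APOE3 replicate 5 (3.87 CPM; others 2.41 to 2.78) and in APOE4 replicate 5 (1.57 CPM; others 1.06 to 1.22), and Tmem72, a choroid plexus gene, was at 9.22 CPM in APOE3 replicate 5 (others 4.81 to 6.44). In APOE2, the far values were Eif3j2 at 5.87 CPM in replicate 2, Sytl1 at 6.2 CPM in replicate 3, Ptprh at 0.405 CPM in replicate 4, Btg2 at 22.1 CPM in replicate 6 and Camk1g at 41.7 CPM in replicate 2. Lgals3bp was at 30.9 CPM in APOE4 replicate 4 (others 22.4 to 25). Near the floor in APOE2, Erdr1 was at 0.0169 CPM in replicate 4 and Serpina3m at 0.0197 CPM in replicate 6, each from 1 read with 0 reads in the other 5 libraries, and Serpina3f was at 0.136 CPM in replicate 2 (others 0.0337 to 0.0616).

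The APOE4 against APOE3 difference was itself different between the sexes for 2 genes in edgeR, where DESeq2 called 44 and limma voom 6. Btg2, an antiproliferative immediate early gene, had log2 fold changes of -1.33 in females and 1.40 in males, a difference of -2.73 (SE 0.35, adjusted p = 0.0321). Its mean was 38.8 CPM in APOE3 females, 12.5 in APOE3 males, 15.4 in APOE4 females and 33.2 in APOE4 males (n = 3 each). Spred2, an inhibitor of Ras signalling, had log2 fold changes of 0.33 in females and -0.25 in males, a difference of 0.57 (SE 0.09, adjusted p = 0.0371).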

How the results depend on the processing

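Leaving out genes in windows with an excess of calls was chosen after seeing the data, and all other alternatives before. No paired analysis was possible because the labels give no replicate numbers shared between groups. The rule-named genes kept their direction and side of the threshold in 1922 of 1938 values, and 16 values were weaker. These values cover 70 pairs of a gene and a comparison, and a gene named in several comparisons counts in each. Called list members were weaker in 175 of 1261 values over 45 pairs of a gene and a comparison, and uncalled ones passed in 64 of 1249. None of these reversed in the alternatives run. Calls ended for 17 named genes in at least 1 fit without a library, among them Amigo2 in APOE4 against APOE3 (14 of 18 fits). DESeq2 called 720, 1215 and 141 of the genes called in APOE2 against APOE3, APOE2 against APOE4 and APOE4 against APOE3.

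In that order, glmTreat called 289, 341 and 55 genes and an adjusted p under 0.01 gave 449, 677 and 90 (665 for any genotype), by construction fewer. Leaving out genes in the windows left 380 for APOE2 against APOE3 and 94 for APOE4 against APOE3, of which 38 and 6 have no position. For the latter DESeq2 called 261. Females and males differed in 53 genes without a filter and 55 in DESeq2. The interaction had 239 genes without a filter, 1 at 1 CPM in 6 libraries, 24 in DESeq2 and 1 in limma voom. APOE2 against APOE4 in males gave 300 genes from the 6 libraries alone. The lists called were 0, 0 and 0 with an estimated correlation, 0, 1 and 1 by directional fry, 20, 29 and 4 by mixed fry, and 5 and 7 at 1 CPM in 6 libraries for the last comparisons. The odds ratio near Apoe reversed to 1.75 (10 Mb, APOE2 against APOE3), 1.11 (1 Mb) and 1.33 (10 Mb, APOE2 against APOE4). Split controls gave 12 and 14 shared genes. Except for the stricter tests and smaller sets, the cause was not tested.

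Without 1 library, counts ranged from 947 to 1903 for APOE2 against APOE4 (highest without APOE4 replicate 5). Within sexes for APOE4 against APOE3 they ranged from 48 to 72 in females (48 without APOE3 replicate 5, 51 without APOE4 replicate 3) and from 37 to 50 in males (37 without APOE3 replicate 3, 38 without replicate 1). For the interaction they ranged from 0 to 4 (4 without APOE4 replicate 1, 1 without APOE2 replicate 6 or APOE3 replicate 6). Lists ranged from 5 to 9 for APOE2 against APOE4 (5 without APOE2 replicate 5, APOE4 replicate 1 or 6) and from 8 to 15 for APOE4 against APOE3 (8 without APOE4 replicate 5). The Apoe log2 fold change ranged from -0.22 to -0.12 for APOE2 against APOE4. Folds near 1.25 are at the limit of this depth and n, where the APOE2 against APOE3 simulation recovered 46% of planted genes.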

Other observations

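The test of neighbours in the sex and interaction comparisons and the splits of the libraries, except those for APOE4 against APOE3 over both sexes, were set before their results were seen; the other tests were chosen after, and 3 of them, on the isoform, on the whole fall of Hspa8 and on chromosome 12, were reworded after the result. Several cell type and immune lists that camera did not call still held genes that changed in APOE2 against APOE3. Among ependymal genes of motile cilia, Tekt1 rose from 2.73 to 4.84 CPM (log2 fold change 0.83, SE 0.10, n = 6 each), whereas Ccdc153 was lower, at 1.94 against 3.90 CPM (-1.01, SE 0.12). Among interneuron genes the serotonin receptor Htr3a was lower, at 4.28 against 7.69 CPM (-0.84, SE 0.08), while Gad2, which makes GABA, rose from 293 to 339 CPM (0.21, SE 0.06). In the complement list Cd59a, which blocks the membrane attack complex, was lower, at 6.23 against 13 CPM (-1.08, SE 0.09). These genes were chosen after their values were seen, and their lists had adjusted p = 0.372, 0.316 and 0.109. Without genes in windows camera called the interneuron list higher (adjusted p = 0.0206 with the preset correlation). It also called the interferon response lower (0.00077) and the unfolded protein and integrated stress responses higher (0.0283). With all genes these last lists had camera adjusted p = 0.0507 and 0.101. An estimated correlation was not run without the window genes. Tekt1, Ccdc153 and Htr3a lie in windows with an excess of called genes.

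Microglial Tyrobp, an adaptor of TREM2, stood at 13.9 CPM in APOE4 and 16.8 CPM in APOE3 (log2 fold change -0.27, SE 0.07) and did not pass in edgeR (adjusted p = 0.0585). In that comparison DESeq2 called 1 member of the homeostatic and 1 of the disease-associated microglia list, where edgeR called 0. Beside Apoe on chromosome 7, the incretin receptor Gipr was lower in APOE2 than in APOE4 by a log2 fold change of -0.68 (SE 0.10) and the poliovirus receptor Pvr by -0.40 (SE 0.10). Hemoglobin Hbb-bs stood at 66.7 CPM in APOE2, 45.5 in APOE3 and 39.2 in APOE4 and did not pass for APOE2 against APOE4 in edgeR (adjusted p = 0.106). Of 8 blood list members in that comparison, edgeR called 0 over all genes, DESeq2 called 1, and 7 passed when adjusted over the list alone.

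Genes called in APOE2 against APOE3 lay beside one another, with 146 neighbouring pairs, above the highest of 47 in permuted calls, which argues against chance placement. As many genes by smallest p from the sex and interaction tests held 40 and 35 pairs. This argues against neighbours moving together as often as 146 pairs in any comparison of these libraries. Both counts were above the median of 27 in permuted calls, so some joint movement is not excluded. Those tests called 25 and 0 genes, so they cannot show whether genes that truly respond lie beside one another. Copies that gained reads in APOE2 had their parent in a window in 82.6% of cases, though the parent was called lower for only 10 of 23, a candidate explanation being sequence variants of the APOE2 line against the reference inside the windows. Around Apoe, 2 of 115 genes within 5 Mb and 17 of 263 within 10 Mb were called (odds ratios 0.442 and 1.75). The window from 20 to 30 Mb of chromosome 7, which begins just past Apoe, held 22 called of 152 tested genes. The 342 called genes placed outside the windows may include a response to the isoform, but the labels separate no lines within a genotype, so the isoform and the line cannot be told apart.

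For Hspa8 and other genes that fell while copies rose, the summed counts of Hspa8 and its copies had a log2 fold change of -0.81 (SE 0.06) against -2.99 for Hspa8 alone, which is consistent with reads counted on a copy as part of the fall. Whether they make the whole fall cannot be told apart from a lower level, since reads left out for matching several places would leave the same mark. Over 10 such families the median parent log2 fold change was -0.80 and the median of the sums -0.32, and no biological explanation of the remainder was tested.

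Serpina3n was higher in APOE4, and reactive astrocytes at a higher level would raise their other genes too, but the other 25 had a median log2 fold change of 0.034 (SD 0.166), far below the 2.74 of Serpina3n. Of its 16 neighbours within 1 Mb, 5 were called, all of the Serpina3 family (Fisher's exact test, two-sided p = 1.01e-07). Of 96 other genes between 100 and 110 Mb of chromosome 12, edgeR called 0, with 9 at an unadjusted p under 0.05, and DESeq2 called 1. These counts are for APOE4 against APOE3 alone, where Ifi27l2a had a log2 fold change of 0.71 (SE 0.19) and Ifi27 of 0.07 (SE 0.06). In APOE2 against APOE4 edgeR called Ifi27l2a (adjusted p = 0.00232). It stood at 0.731 CPM in APOE2, 0.855 CPM in APOE3 and 1.41 CPM in APOE4. Farther along chromosome 12, Ighg2c (from 113285325) and Ighm (from 113418558) were lower in APOE4 than in APOE3. Their log2 fold changes were -5.72 (SE 0.26) and -0.82 (SE 0.09), and both lay outside windows with an excess of calls. Whether they share a cause with the Serpina3 genes was not tested. A stretch of chromosome 12 that differs in the APOE4 line and an effect of the APOE4 isoform on Serpina3n cannot be told apart, since a stretch no longer than the Serpina3 cluster would leave the genes around it uncalled.

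Other splits of the libraries were counted for each comparison, up to 100 including the real one. The values argue against chance for APOE2 against APOE3, where the real 738 genes was the largest and the highest other split gave 5. They also do so for APOE2 against APOE4 (1 split of 100 as large, highest other 587) and for APOE4 against APOE3 (1 of 100, highest other 9). Chance is not excluded, since 100 splits with the real one among them cannot give a share below 1 of 100. For any genotype 2 of 100 were as large as 1146, with the highest other at 1207. Females against males had 3 of 100 splits as large as 25. The highest other split gave 1105, far above the real 25, and the cause was not tested. For the interaction the 100 of 100 splits as large say nothing about chance, since no split can give fewer than the real 0 (highest other 540). For the lists chance cannot be excluded, since 58 of 100 splits called at least 12 for APOE2 against APOE3 (highest 25), 87 at least 8 for APOE2 against APOE4 (27) and 31 at least 13 for APOE4 against APOE3 (23). Within a sex 10 splits are too few for a share under 0.05: for APOE2 against APOE3 the real 382 and 368 genes in females and males stood against a highest other of 0 and 0, for APOE2 against APOE4 the real 539 and 454 against 1 and 678, with 2 splits as large in males, and for APOE4 against APOE3 the real 80 and 67 against 0 and 0.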
